A study of Homo sapiens with 9 samples.

How the data were processed

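Poly(A) RNA was sequenced from MDA-MB-231 cells, an established line from a triple negative breast cancer, that had been transduced with lentivirus and sorted by fluorescence. Per the labels, the cells carried RFP (red fluorescent protein, the control), a substituted form of Kir2.1 joined to EGFP, or Kv1.5 followed by EGFP. Kir2.1, encoded by KCNJ2, is an inwardly rectifying potassium channel. Kv1.5, encoded by KCNA5, is a voltage-gated potassium channel. Per the labels' protocols, RNA came from 3 separate biological replicates of each line, libraries were made with a stranded mRNA kit and reads were single-end. Whether the replicates came from separate transductions is not given in the sources used here, so the p-values measure the spread between cultures of each transduced line and not between independently made lines.

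The authors' deposited table holds raw counts per gene, as whole numbers, for 60715 Ensembl genes. FastQC, Trimmomatic, STAR, edgeR and the genome build GRCh38 are named in the submitters' processing notes, without versions. The counting step, its strand setting and the annotation release are not given in the sources used here. Without a stated strand setting, reads of a gene and its antisense partner cannot be told apart. The table has columns for 8 libraries: 3 RFP, 3 Kir2.1 and 2 Kv1.5 (replicates 2 and 3). Kv1.5 replicate 1 was not analysed here. The authors' deposited comparison tables, against RFP for each channel, hold log2 fold changes, log2 CPM, p-values with adjusted p-values, and a signed ranking score, under column names that edgeR's glmTreat gives. The fold they tested against is not given in the sources used here. The adjusted values in these tables equal a Benjamini-Hochberg adjustment over the listed genes alone, with a largest relative difference of 0.00664, and so are not comparable with an adjustment over all genes.

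Symbols came from a gene name table for 60445 of the 60715 IDs, and positions (GRCh38) from GENCODE 29 for 58497. Counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr by group left 16687 genes, TMM factors scaled the libraries, and dispersions and quasi-likelihood fits were robust. All 8 libraries entered a single fit with group as the term, giving 5 residual degrees of freedom. The comparisons were Kir2.1 against RFP, Kv1.5 against RFP and Kv1.5 against Kir2.1. Genes with a Benjamini-Hochberg adjusted p under 0.05 in the quasi-likelihood F-test were called changed, and those with a fitted log2 fold change of at least 1 in size were also counted as changed by more than 2-fold. The standard error of a log2 fold change was derived from its F statistic. Levels are CPM on TMM-scaled libraries, as mean ± SD. The design had assumed 9 libraries, and the rules were applied to the 8 in the table.

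Before the data were examined, 26 gene lists, the tests, the alternatives and the rule for named genes were fixed. The 24 lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over lists within a comparison. Camera with an estimated correlation and fry were alternatives. Named genes were the channel genes, the 6 genes with the largest rise and the 6 with the largest fall (4 and 4 between the libraries labelled Kv1.5 and Kir2.1) among called genes with a mean of at least 5 CPM and no overlap between groups (2 libraries labelled Kv1.5 in place of 3), the 3 called members with the largest change (2 in that comparison) of up to 6 lists, and CDH11, DUSP6 and MKI67. Lists qualified by a called camera test or by at least 25% of tested members past the threshold, in order of camera p. Not every gene that the rule names is reported here. Other genes named below are members of the fixed lists and were picked after their values were seen. Where a group had 0 counts, a fold is a lower bound from 3 counts over the group. With 1 to 3 counts it is a ratio with an exact 95% interval. Bounds and intervals cover counting error only.

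The alternatives were RLE and upper quartile scaling, 2 other filters, DESeq2 1.42.0, limma voom, only the 2 groups compared, the replicate number as a block, each library left out, an adjusted p under 0.01, the channel genes left out and glmTreat against a fold of 1.2. Unchanged groups were simulated 40 times against shared RFP libraries. Medians over windows of 50 neighbouring genes, the last of a chromosome holding more, with a mean of at least 5 CPM were set against 1000 permuted gene orders, a test chosen after the gene counts were seen. A loess fit on GC content and length of the longest GENCODE 29 transcript was taken off as a check.

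The tests were checked on simulated counts, in 5 runs with, over the runs, 250 changed genes of each fold size. For Kir2.1 against RFP, with 16243 to 16294 genes tested, 4% of genes changed 1.5-fold were recovered, 34.4% at 2-fold, 79.6% at 4-fold and 91.6% at 8-fold. For Kv1.5 against RFP, with 16257 to 16292 genes tested, the shares were 2%, 20.8%, 74% and 91.6%. For Kv1.5 against Kir2.1, over as many genes, they were 0.4%, 20%, 73.6% and 90.4%. False calls made up 7.1%, 7.1% and 7.2% of calls in these comparisons, above the nominal 5%. Each run changed a far smaller share of genes than was called in the real data, so the recovered shares do not measure sensitivity there. The list of 20 ERK output genes raised 1.5-fold in simulated Kv1.5 libraries gave an adjusted p of 2.23e-10 with the preset correlation and 0.0464 with the estimated correlation, over 16687 genes. Genes were simulated independently of each other, so that check does not cover lists whose members vary together. In simulated Kir2.1 libraries with chromosome 12 lowered to 0.65, all 11 windows of that chromosome and no others lay 0.4 or more from 0, over 10678 genes.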

Results

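The data are gene counts from 8 libraries of MDA-MB-231 cells carrying RFP (n = 3), the potassium channel Kir2.1 (n = 3) or a construct labelled Kv1.5 (n = 2). Library totals ran from 30970235 to 42753422 counts. Libraries of a group correlated at r = 0.972 to 0.992 across genes on the log2 CPM scale, the lowest being the Kv1.5 pair. RFP and Kir2.1 libraries correlated at 0.935 to 0.951, Kir2.1 and Kv1.5 libraries at 0.943 to 0.965, and RFP and Kv1.5 libraries at 0.909 to 0.921. These are correlations across genes, which are not independent replicates. Counts of replicate libraries differed by far more than sampling noise, with a chi-square of 27.1 to 177.7 per degree of freedom, so no library was a copy of another.

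The channel genes check the labels. KCNJ2 (ENSG00000123700.5, chromosome 17, 70168673 to 70180048 on GRCh38) stood at 842.7, 1384 and 1189 CPM in the Kir2.1 libraries, against at most 0.0863 CPM in an RFP library and 0.105 CPM in a library labelled Kv1.5. Its rise over RFP was 14.86 on the log2 scale (SE 0.51, adjusted p = 5.68e-09). By counts it was 33130 times higher, and 92390 times (95% interval 16580 to 3649000) without RFP replicate 3, which left 1 RFP count. KCNA5 (ENSG00000130037.5, chromosome 12, 5043989 to 5046788) had 0 counts in both libraries labelled Kv1.5 and in all 3 RFP libraries, and 1 count in Kir2.1 replicate 1. Over the 79896400 counts of the libraries labelled Kv1.5, 0 counts allow up to 0.0390 CPM after TMM scaling. The construct label of these libraries was therefore not borne out by KCNA5. They are called the libraries labelled Kv1.5, and Kv1.5 in the name of a comparison, library or replicate stands for that label.

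**Figure D1:**
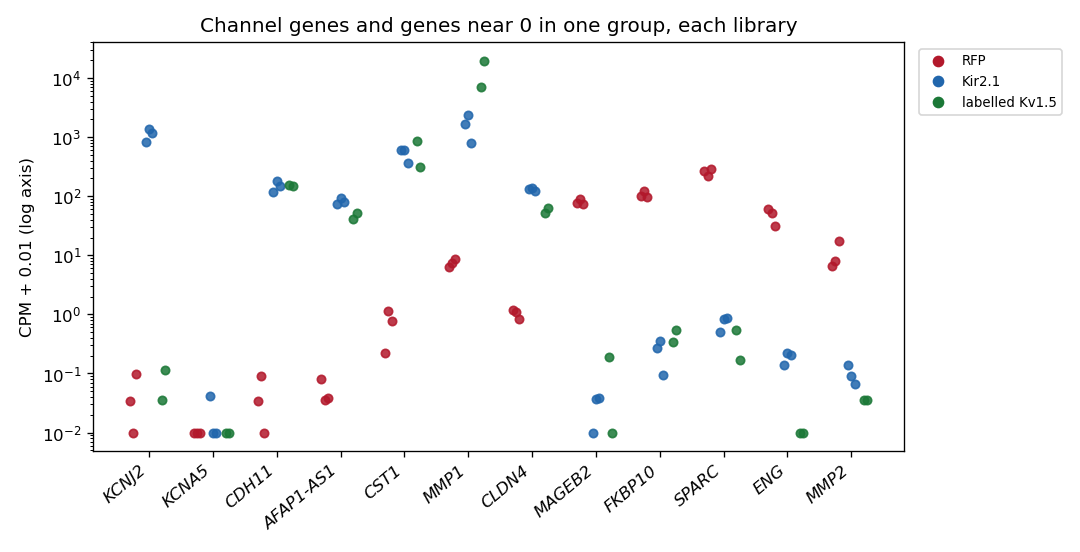
Level of 12 genes in each library, in CPM plus 0.01 on a log axis. Each point is a library, coloured by group. KCNJ2 is at 842.7 CPM or more in the Kir2.1 libraries alone, KCNA5 lies at or near 0 in all 8, and CDH11, AFAP1-AS1, CST1, MMP1 and CLDN4 on one side and MAGEB2, FKBP10, SPARC, ENG and MMP2 on the other separate RFP from both other groups.

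The comparison of Kir2.1 with RFP asks which genes differ in cells made to overexpress the inward rectifier, which carried EGFP in place of RFP. Apart from KCNJ2, the largest differences were genes near 0 in one group. CDH11, a cadherin of mesenchymal cells (chromosome 16, 64943753 to 65126112), stood at 146 ± 31.0 CPM in Kir2.1 and 0.0342 ± 0.0404 CPM in RFP (n = 3 each), a rise of 11.90 on the log2 scale (SE 0.42, adjusted p = 6.26e-09), over 4 RFP counts in all. AFAP1-AS1, a long noncoding RNA antisense to AFAP1, rose by 10.77 to 82.0 ± 9.34 CPM, with the strand of counting not stated. CST1, a secreted cystatin with close paralogs, rose by 9.57 to 525 ± 145 CPM, and MXRA8, a membrane adhesion protein, by 9.34 to 35.9 ± 3.69 CPM. CCBE1 was 857 times higher by its counts (95% interval 293 to 4161) and TP53I11 825 times (228 to 6816). In the other direction MAGEB2, a cancer-testis antigen, was 4160 times lower by its counts (1151 to 34359). FKBP10, a collagen chaperone, fell 459-fold from 108 ± 13.2 CPM in RFP, and SPARC, a matrix glycoprotein, fell 354-fold from 258 ± 37.0 CPM to 0.720 ± 0.206 CPM. TM4SF18 fell 367-fold, ENG, the TGF-beta co-receptor endoglin, 259-fold, and MMP2, a gelatinase, 117-fold. By counts CDH11 was 4253 times higher, and 11360 times (2039 to 448900) without RFP replicate 2. Without RFP replicate 1 the ratio of AFAP1-AS1 went from 1893 to 3004 (831.3 to 24810), that of CCBE1 to 1633 (292.8 to 64530) and that of TP53I11 to 523.5 (144.7 to 4327). Without RFP replicate 3, which held all its RFP counts, TP53I11 was at least 383.2-fold higher.

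Matrix proteases and their inhibitors had the lowest p of the tested lists: 11 of 25 tested members rose and 2 fell (12 and 2 adjusted over the list alone; camera adjusted p = 9.66e-05, and adjusted p = 0.315 with an estimated correlation). MMP1, the interstitial collagenase, rose by 7.74 from 7.52 ± 1.13 to 1610 ± 806 CPM, and PLAT, the tissue plasminogen activator, by 2.37 to 513 ± 38.7 CPM, while MMP2 fell. Of 14 epithelial markers 5 rose and 2 fell (6 and 3 over the list alone; adjusted p = 0.000713, and adjusted p = 0.191 with an estimated correlation). The tight junction genes CLDN4 and CLDN7 rose by 6.97 and 2.19 and the keratin KRT19 by 2.31, whereas the splicing factor ESRP1 fell. Type I interferon stimulated genes had 7 of 27 members higher and none lower (the same over the list alone; adjusted p = 0.00486, and adjusted p = 0.832 with an estimated correlation). IFI27 rose by 5.63 to 46.5 ± 5.85 CPM, BST2 by 3.93 and ISG15 by 1.18, and the call of this list ended without RFP replicate 1 and with fry (adjusted p = 0.151). Inflammatory cytokines and NF-kB targets went both ways, with 6 of 26 higher and 4 lower (8 and 4 over the list alone; adjusted p = 0.0236, and adjusted p = 0.832 with an estimated correlation). ICAM1, a leukocyte adhesion molecule, rose by 2.83 to 269 ± 46.5 CPM. CSF3 and IL1B fell 14.1-fold and 7.89-fold (adjusted p = 0.0444 and 0.0393), from RFP levels of 330 ± 380 and 84.7 ± 90.3 CPM. Each of these calls was lost under 9 of 18 alternatives, among them each Kir2.1 or Kv1.5 library left out, and without RFP replicate 3 the log2 fold changes were -2.29 for CSF3, -1.62 for IL1B and 4.61 for BST2. The inflammatory list lost its call without RFP replicate 1 or 2, with limma voom, with fry, and with the filter of 1 CPM, and the epithelial list with limma voom.

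Integrins had 5 of 14 members higher and none lower, but no list call (6 and 0 over the list alone; adjusted p = 0.107). ITGA10 rose by 2.29, ITGA2 by 1.22 and ITGA5 by 1.10. The ITGA2 call was lost without RFP replicate 1 or 2 or without Kir2.1 replicate 2 or 3. Among basal epithelial markers typical of MDA-MB-468, another breast line of the study, 4 of 9 rose and 2 fell (4 and 3 over the list alone; adjusted p = 0.113). LCN2 rose by 3.92 to 19.6 ± 8.58 CPM, a call lost without Kir2.1 replicate 2 and with no filter on low counts and a change of 6.01 without RFP replicate 3, and KRT81, a hair keratin with close paralogs, fell from 387 to 89.7 CPM. DUSP6, a phosphatase induced by ERK signalling, rose by 0.93 (SE 0.25, adjusted p = 0.0219), a call lost without RFP replicate 1 or without Kir2.1 replicate 2 or 3. MKI67, a marker of dividing cells, stood at 876 ± 178 CPM in Kir2.1 and 997 ± 124 CPM in RFP (adjusted p = 0.798). None of 25 mitosis genes passed the threshold (0 over the list alone; adjusted p = 0.151), and 2 of 24 replication genes were lower (1 over the list alone; adjusted p = 0.151). Fibroblast and endothelial markers had 4 of 7 members higher and 1 lower (4 and 1 over the list alone; adjusted p = 0.246), with S100A4 at 524 CPM in Kir2.1 and 70.3 CPM in RFP, where single libraries ran from 18.7 to 110 CPM, a call lost with no filter on low counts.

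In all, 3418 of 16687 genes (20.5%) were called changed with edgeR's quasi-likelihood test, 2040 higher and 1378 lower. By more than 2-fold 2234 changed (1382 higher, 852 lower). The groups did not overlap for 44.7% of genes, against 10% by chance. Without RFP replicate 2 the count was 2143, and without Kir2.1 replicate 2 it was 1975, while the number of called lists went from 4 to 2 without RFP replicate 1 and to 7 without RFP replicate 3. The authors' deposited table for this comparison lists 731 genes higher and 408 lower, all in the same direction in the refit. The refit used the authors' deposited counts, and log2 fold changes differed by at most 0.0133, so the shared directions are no separate evidence.

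The comparison of the libraries labelled Kv1.5 with RFP asks which genes differ under that label. CDH11 stood at 151 ± 5.02 CPM (n = 2), a rise of 11.95 on the log2 scale (SE 0.43, adjusted p = 1.42e-08). MMP1 rose by 10.78 to 13245 ± 8762 CPM, with 7049 and 19440 CPM in replicates 2 and 3. CST1 and AFAP1-AS1 rose by 9.70 and 9.95 and CXCR4, a chemokine receptor, by 9.43. SLITRK1, a neuronal membrane protein with 0 counts in RFP, was at least 499.6-fold higher. ENG had 0 counts in the libraries labelled Kv1.5 and was at least 1255-fold lower, and SLC13A4, a sulfate transporter, at least 221.7-fold lower. PTPRN2 was 2173 times lower by its counts (95% interval 390 to 85845) and NLRP2 485 times (166 to 2352). MAGEB2 fell 850.1-fold and SPARC 730.4-fold. With KCNA5 at 0 counts, these directions belong to the libraries as labelled. Left-out libraries moved some log2 fold changes: CST1 to 8.80 and SPARC to -10.64 without Kv1.5 replicate 2, and MMP1 to 9.87, SPARC to -8.89 and MAGEB2 to -8.77 without replicate 3. By counts CDH11 went from 4333 to 11580 times higher (2078 to 457400) without RFP replicate 2, and AFAP1-AS1 from 1066 to 1691 times (467.9 to 13970) without RFP replicate 1. SLITRK1 was at least 317.2-fold higher without RFP replicate 1. Without Kv1.5 replicate 2, ENG, SLC13A4, NLRP2 and MAGEB2 were at least 619.6-fold, 109.5-fold, 239.2-fold and 1015-fold lower and PTPRN2 1073 times by its counts (192.4 to 42380). Without replicate 3, ENG, SLC13A4 and PTPRN2 were at least 635.6-fold, 112.3-fold and 366.7-fold lower and NLRP2 245.4 times by its counts (83.86 to 1191).

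Of 26 tested inflammatory cytokines and NF-kB targets, 19 were higher and none lower (20 and 0 over the list alone; camera adjusted p = 5.92e-12, and adjusted p = 0.186 with an estimated correlation). IL1A rose by 4.44 from 11.4 ± 3.17 to 249 ± 69.2 CPM, ICAM1 by 4.38 to 787 ± 309 CPM and the neutrophil chemokine CXCL8 by 3.86 to 3706 ± 43.1 CPM, a call lost with no filter on low counts and a change of 4.74 without RFP replicate 3. Values of IL6, CXCL1 and CSF3, which did not pass, were 1.71, 2.06 and -1.57. Unfolded protein and integrated stress response genes had 15 of 24 members higher and 1 lower (16 and 1 over the list alone; adjusted p = 3.34e-06, and adjusted p = 0.186 with an estimated correlation). CHAC1, which degrades glutathione, rose by 3.23, the pseudokinase TRIB3 by 3.15 and PPP1R15A, a regulatory subunit that directs a phosphatase to eIF2 alpha, by 2.66, while PHGDH fell (log2 fold change -0.98), a call lost without RFP replicate 2 or Kv1.5 replicate 2. The chaperone HSPA5 rose by 1.71, with 1134 and 3110 CPM in replicates 2 and 3, and by 0.80 without replicate 3, where its call was lost. ERK output genes had 10 of 20 higher and 1 lower (the same over the list alone; adjusted p = 0.000286, and adjusted p = 0.186 with an estimated correlation), with IER3 at 3054 ± 536 CPM, 6.49-fold above RFP, SPRY2 5.67-fold, PHLDA1 5.24-fold and DUSP6 4.73-fold. CCND1 fell (log2 fold change -0.86), a call lost without Kv1.5 replicate 2. Of 20 immediate early genes 9 were higher and none lower (10 and 0 over the list alone; adjusted p = 0.000286, and adjusted p = 0.438 with an estimated correlation). JUNB rose by 3.19, IER2 by 2.12 and ATF3 by 1.60, the last a call lost without either library labelled Kv1.5 or without Kir2.1 replicate 2.

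Genes of cell division were lower. Of 24 replication and S phase genes 20 fell and none rose (the same over the list alone; adjusted p = 2.2e-10, and adjusted p = 0.186 with an estimated correlation), with log2 fold changes of -2.32 for UHRF1, -2.19 for MCM5 and -1.80 for MCM6. Of 25 mitosis genes 18 fell and none rose (23 and none over the list alone; adjusted p = 1.34e-07, and adjusted p = 0.438 with an estimated correlation). KIF20A fell 8.33-fold, MKI67 5.16-fold (log2 fold change -2.37, SE 0.54, adjusted p = 0.00764) and ASPM 4.94-fold, and the KIF20A call was lost without Kir2.1 replicate 3 and with no filter on low counts. In replicates 2 and 3, MKI67 stood at 318.8 and 67.7 CPM, KIF20A at 60.9 and 5.21 CPM and ASPM at 57.4 and 14.3 CPM. Without replicate 2 the log2 fold changes were -3.88 for MKI67, -5.72 for KIF20A and -3.63 for ASPM, and without replicate 3 they were -1.65, -2.18 and -1.62. Cholesterol synthesis genes had 13 of 23 members lower and 1 higher (14 and 1 over the list alone; adjusted p = 0.000604, and adjusted p = 0.548 with an estimated correlation). Log2 fold changes were -1.87 for MSMO1 and -1.52 for HMGCS1, and the list's fry adjusted p was 0.0699. Both calls were lost without RFP replicate 3, where that of MSMO1 was -1.10, without Kir2.1 replicate 2 and without either library labelled Kv1.5. The MSMO1 call was also lost with no filter on low counts, and the HMGCS1 call without RFP replicate 2 and with RLE factors. Hypoxia and glycolysis genes had 13 of 29 lower and 3 higher (13 and 4 over the list alone; adjusted p = 0.0308, and adjusted p = 0.438 with an estimated correlation). PKM and GAPDH fell (log2 fold change -1.44 and -1.32), and the list call ended without RFP replicate 3, or without either library labelled Kv1.5.

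Matrix genes divided. Among proteases and inhibitors 13 of 25 rose and 4 fell (the same over the list alone; adjusted p = 0.000604, and adjusted p = 0.186 with an estimated correlation), with ADAMTS1 up by 4.97 and PLAT by 3.45, and ADAM12 lower (log2 fold change -4.79). ADAMTS1 stood at 84.2 and 328 CPM in replicates 2 and 3, and rose by 5.64 without replicate 2 and 3.67 without replicate 3. MMP2, with 2 counts in these libraries, was 396 times lower by its counts (95% interval 109.4 to 3274). Collagens and matrix glycoproteins had 10 of 25 lower and 3 higher (11 and 3 over the list alone; adjusted p = 0.0015, and adjusted p = 0.395 with an estimated correlation). COL1A1, LAMA4 and COL7A1 fell (log2 fold change -5.32, -3.81 and -3.22), whereas the laminin chain LAMB3 rose by 2.05. That of COL1A1 was -6.17 without Kv1.5 replicate 2. Epithelial markers had 5 of 14 higher and 2 lower (the same over the list alone; adjusted p = 0.00795, and adjusted p = 0.186 with an estimated correlation), with CLDN4 and CLDN7 up by 5.78 and 3.70 and KRT8 lower (log2 fold change -1.64). The call of the epithelial list was lost with limma voom and with no filter on low counts. Interferon stimulated genes had 6 of 27 higher and 2 lower (the same over the list alone; adjusted p = 0.0203, and adjusted p = 0.795 with an estimated correlation), a call that ended without RFP replicate 1 or Kv1.5 replicate 2, with limma voom and with fry (adjusted p = 0.153). Among all tested genes 33.7% were called changed in this comparison, so members of this list were not called more often than genes at large. LAPTM5, a leukocyte marker that the RFP libraries also express at 188 CPM, stood at 63.5 and 15.6 CPM in the libraries labelled Kv1.5.

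Altogether 5624 genes (33.7% of those tested) were called changed with edgeR's quasi-likelihood test, 3028 higher and 2596 lower. By more than 2-fold 3851 changed (2112 higher, 1739 lower). Groups did not overlap for 54.2% of genes, against 20% by chance for 2 libraries against 3. The authors' deposited table lists 1239 genes higher and 939 lower, all in the same direction in the refit. The refit used the authors' deposited counts, and log2 fold changes differed by at most 0.0104, so this is no separate evidence.

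Camera made no call for the following lists in the comparisons given. The 14 cadherins and protocadherins had 2 higher and 3 lower in Kir2.1 (3 and 5 over the list alone, adjusted p = 0.626) and 4 higher and 5 lower in the libraries labelled Kv1.5 (4 and 6 over the list alone, adjusted p = 0.983). The 16 mesenchymal markers had 2 higher and 6 lower in Kir2.1 (2 and 6 over the list alone, adjusted p = 0.747) and 3 higher and 6 lower in the libraries labelled Kv1.5 (4 and 6 over the list alone, adjusted p = 0.472). The 24 calcium and NFAT responsive genes had 3 higher and 4 lower in Kir2.1 (4 and 5 over the list alone, adjusted p = 0.957) and 7 higher and 4 lower in the libraries labelled Kv1.5 (8 and 5 over the list alone, adjusted p = 0.474). The 21 potassium channels, KCNJ2 among them, had 4 higher and 5 lower in Kir2.1 (5 and 5 over the list alone, adjusted p = 0.668) and 5 higher and 4 lower in the libraries labelled Kv1.5 (5 and 4 over the list alone, adjusted p = 0.68). The 35 other ion channels and pumps had 4 higher and 2 lower in Kir2.1 (4 and 2 over the list alone, adjusted p = 0.854) and 5 higher and 6 lower in the libraries labelled Kv1.5 (6 and 6 over the list alone, adjusted p = 0.983). The 26 oxidative phosphorylation genes had 1 higher and 1 lower in Kir2.1 (1 and 0 over the list alone, adjusted p = 0.807) and 1 higher and 4 lower in the libraries labelled Kv1.5 (1 and 3 over the list alone, adjusted p = 0.499). The 20 YAP and TEAD targets had 0 higher and 4 lower in Kir2.1 (0 and 4 over the list alone, adjusted p = 0.0911) and 1 higher and 5 lower in the libraries labelled Kv1.5 (1 and 5 over the list alone, adjusted p = 0.369). The 22 TGF-beta responsive genes had 4 higher and 5 lower in Kir2.1 (6 and 7 over the list alone, adjusted p = 0.957) and 7 higher and 5 lower in the libraries labelled Kv1.5 (7 and 5 over the list alone, adjusted p = 0.983). The 29 WNT and NOTCH pathway genes had 5 higher and 5 lower in Kir2.1 (5 and 6 over the list alone, adjusted p = 0.985) and 8 higher and 6 lower in the libraries labelled Kv1.5 (8 and 8 over the list alone, adjusted p = 0.945). In these libraries, the 14 integrins had 5 higher and 0 lower (6 and 0 over the list alone, adjusted p = 0.369), the 9 MDA-MB-468 markers had 4 higher and 1 lower (4 and 1 over the list alone, adjusted p = 0.122), and the 7 fibroblast and endothelial markers had 2 higher and 2 lower (3 and 2 over the list alone, adjusted p = 0.945). Fry called the MDA-MB-468 markers as higher there (adjusted p = 0.0161). The 20 ERK output genes had 5 higher and 0 lower in Kir2.1 (5 and 0 over the list alone, adjusted p = 0.523) and 24 stress response genes had 1 higher and 6 lower in Kir2.1 (2 and 6 over the list alone, adjusted p = 0.161). The 25 collagens and matrix glycoproteins had 8 higher and 8 lower in Kir2.1 (8 and 9 over the list alone, adjusted p = 0.373) and 20 immediate early genes had 1 higher and 1 lower in Kir2.1 (1 and 1 over the list alone, adjusted p = 0.957). The 23 cholesterol synthesis genes had 2 higher and 0 lower in Kir2.1 (1 and 0 over the list alone, adjusted p = 0.957) and 29 hypoxia and glycolysis genes had 2 higher and 2 lower in Kir2.1 (2 and 2 over the list alone, adjusted p = 0.807). Too few members were tested for HEK293T markers (3, led by CRABP2 at 13.2 CPM in RFP) and leukocyte markers (4) to test these lists. Median, mean and test differed in sign for mesenchymal markers (median 0.04, mean -0.05) and ERK output genes (median -0.05, mean 0.18) in Kir2.1, and for potassium channels (median 0.15, mean -0.51) in the libraries labelled Kv1.5, as for some other lists without a call.

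**Figure D2:**
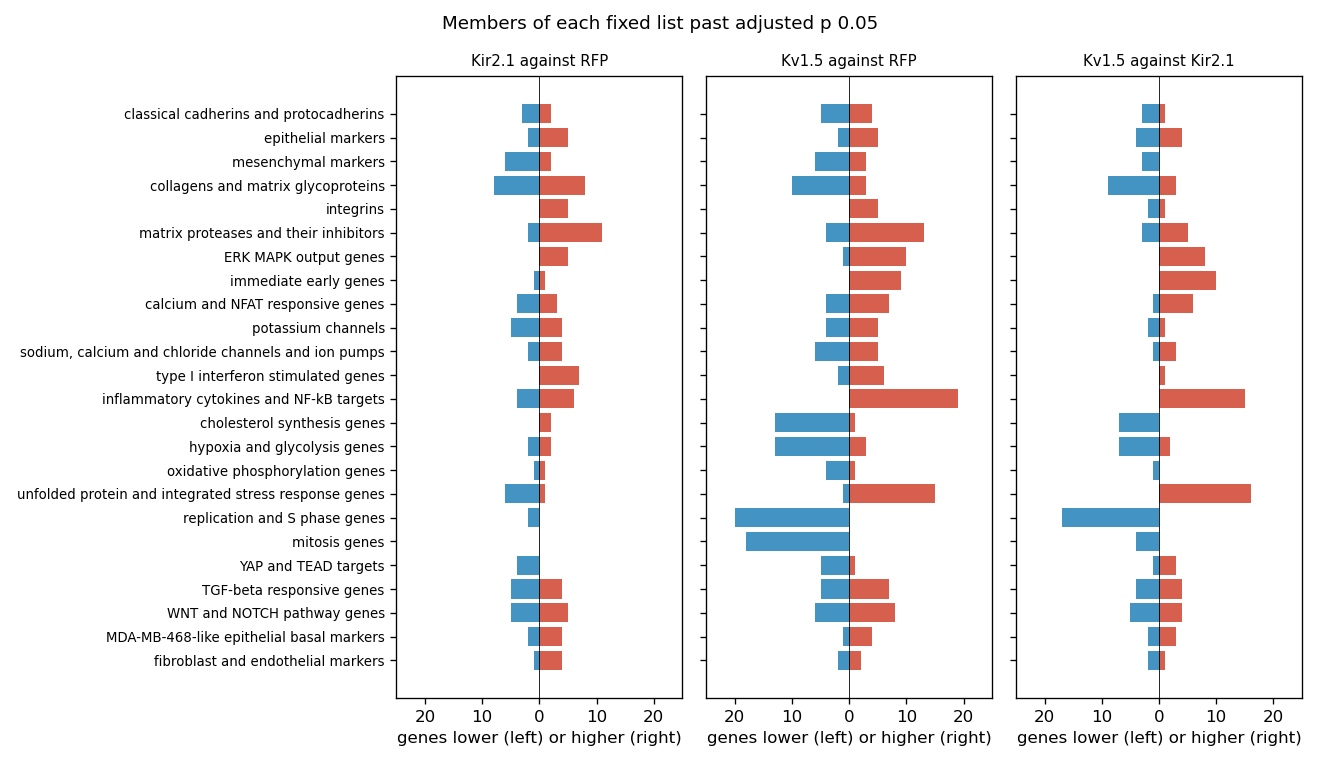
Members of the 24 tested gene lists past an adjusted p of 0.05, in each comparison. Bars to the right count genes that were higher and bars to the left genes that were lower, and Kv1.5 stands for the libraries labelled so. In Kv1.5 against RFP, 19 inflammatory genes are higher and 20 replication and 18 mitosis genes are lower.

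The comparison of the libraries labelled Kv1.5 with Kir2.1 leaves the RFP libraries out of the difference and tests whether the effects against RFP differ. The unfolded protein and integrated stress response list had the lowest camera p, with 16 of 24 members higher and none lower (19 and 0 over the list alone; camera adjusted p = 8.64e-18, and adjusted p = 0.0758 with an estimated correlation). CHAC1 was higher by 3.16 and PHGDH, the first enzyme of serine synthesis, by 3.04. Against RFP, PHGDH had fallen in Kir2.1 (log2 fold change -4.01). Inflammatory genes had 15 of 26 higher (16 over the list alone, with 1 lower; adjusted p = 1.67e-11, and adjusted p = 0.324 with an estimated correlation), with IL1A up by 4.78 and PTGS2, the inducible cyclooxygenase, by 4.33. Replication genes had 17 of 24 lower (22 over the list alone; adjusted p = 6.93e-12, and adjusted p = 0.0941 with an estimated correlation), MCM5 3.97-fold and UHRF1 3.53-fold. Mitosis genes had 4 of 25 lower (16 over the list alone; adjusted p = 4.01e-08, and adjusted p = 0.461 with an estimated correlation), MKI67 4.53-fold and CCNA2 2.34-fold, and the list's fry adjusted p was 0.0808. The MKI67 call was lost without Kir2.1 replicate 2 or 3, and the CCNA2 call without RFP replicate 2, any Kir2.1 replicate or Kv1.5 replicate 3, and with only the 2 groups compared. The log2 difference of MKI67 was -3.69 without Kv1.5 replicate 2 and -1.46 without replicate 3, and that of CCNA2 was -2.21 without Kv1.5 replicate 2.

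Immediate early genes had 10 of 20 higher (11 over the list alone; adjusted p = 9.37e-08, and adjusted p = 0.345 with an estimated correlation), ATF3 by 2.72 and JUNB by 2.40, with the ATF3 call lost without Kv1.5 replicate 3. Cholesterol synthesis genes had 7 of 23 lower (11 over the list alone; adjusted p = 3.75e-06, and adjusted p = 0.454 with an estimated correlation), EBP 3.23-fold, with a fry adjusted p of 0.0808. ERK output genes had 8 of 20 higher (8 over the list alone; adjusted p = 4.07e-05, and adjusted p = 0.0942 with an estimated correlation). Collagens and matrix glycoproteins had 9 of 25 lower and 3 higher (11 and 4 over the list alone; adjusted p = 0.000744, and adjusted p = 0.345 with an estimated correlation). Hypoxia and glycolysis genes had 7 of 29 lower and 2 higher (the same over the list alone; adjusted p = 0.0152, and adjusted p = 0.345 with an estimated correlation), a call that ended without Kv1.5 replicate 2 and with fry (adjusted p = 0.0561).

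Camera called no other list in this comparison, the lowest adjusted p among them being 0.196, for potassium channels. Fry called that list, which includes KCNJ2, as lower (adjusted p = 0.0176). Single genes with large differences included GDF15, a stress-induced cytokine, at 281 ± 110 CPM (n = 2) against 9.75 ± 2.31 CPM (n = 3), a difference of 4.85 (SE 0.35, adjusted p = 1.3e-05). DUSP2, S100P and MMP3 were 33.2-fold, 32.0-fold and 29.6-fold higher, at 6.47, 6.78 and 35.1 CPM in replicate 2 and 65.8, 28.0 and 108 CPM in replicate 3, with the MMP3 call lost without Kir2.1 replicate 3 or Kv1.5 replicate 3. KRT81 was 19.1-fold lower, SCARA3 17.4-fold, RARRES2 15.2-fold and LINC03040 38.4-fold. The RARRES2 call was lost without Kir2.1 replicate 2, that of LINC03040 without Kv1.5 replicate 3, and those of DUSP2, MMP3 and RARRES2 with no filter on low counts. Without Kv1.5 replicate 2 the log2 differences were 5.92 for DUSP2, 5.69 for S100P, 5.48 for MMP3, -5.53 for SCARA3 and -7.44 for RARRES2, and without Kv1.5 replicate 3 they were 2.57, 3.64, 3.85 and -3.43, with RARRES2 7.99-fold lower. That of MMP3 was 6.07 without Kir2.1 replicate 2 and that of LINC03040 -4.38 without Kir2.1 replicate 3. In all, 2801 genes (16.8% of those tested) were called with edgeR's quasi-likelihood test, 1467 higher and 1334 lower. By more than 2-fold 1913 differed (1013 higher, 900 lower). Groups did not overlap for 47.7% of genes, against 20% by chance. The count was 1859, 1384 and 1493 without Kir2.1 replicate 1, 2 and 3, and 1484 without Kv1.5 replicate 3, and for changes of more than 2-fold it was 1248 without Kir2.1 replicate 2 and 2979 without Kv1.5 replicate 2.

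Against RFP, 1369 genes were higher in both other groups and 859 were lower in both, together 65.2% of the genes changed in Kir2.1. Independent lists of these sizes would share 370 and 214 genes, and unchanged groups simulated against shared RFP libraries, with 1.32 calls per run on average, shared at most 1 and 0. That simulated count is chance with no effect and does not measure what shared controls add among real changes. The log2 fold changes had a covariance of 1.46 and a correlation of 0.764 across genes, against a simulated mean covariance of 0.0617 and a simulated correlation of 0.441. The 3 RFP libraries were not split between the comparisons, and part of the excess in shared calls may come from the shared controls. The number of shared genes was 1363 without RFP replicate 2 and 1409 without Kir2.1 replicate 2. CDH11, MMP1, CST1, AFAP1-AS1, MAGEB2, SPARC and ENG were among the shared genes.

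**Figure D3:**
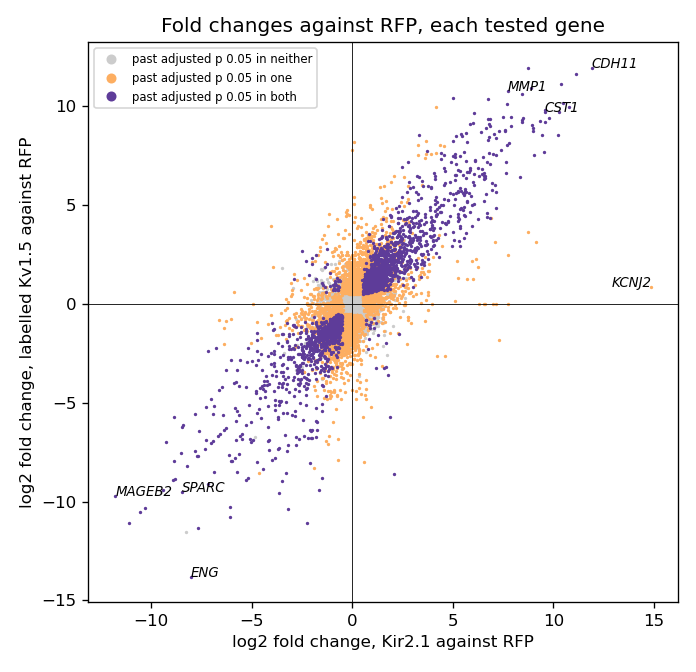
Log2 fold change against RFP of each of 16687 tested genes, in Kir2.1 (horizontal) and in the libraries labelled Kv1.5 (vertical). Colour gives the number of comparisons in which the gene passed an adjusted p of 0.05. Most genes past the threshold in both lie on the rising diagonal, and KCNJ2 lies far to the right near 0 on the vertical axis.

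Fold changes were not evenly spread over the genome. In 204 windows of 50 neighbouring genes (up to 93 in the last window of a chromosome), a test chosen after the gene counts were seen, the SD of window medians was 0.287 for Kir2.1 against RFP and 0.340 for the libraries labelled Kv1.5 against RFP, while 1000 permuted gene orders reached at most 0.100 and 0.134. Medians lay 0.4 or more from 0 on the same side in both comparisons in 26 windows, 19 higher and 7 lower. All 5 libraries of the other groups lay beyond all 3 RFP libraries in 25 of them. As the windows were picked by the fold changes of these same libraries, that count is no separate evidence. The lower windows were 6 neighbouring windows on chromosome 12 (14522 to 67665406) and the last window of chromosome 15 (75843285 to 101724604). Higher windows included 4 neighbouring windows on chromosome 6 (28224886 to 45664349) and 5 that lay between 629640 and 52056171 on chromosome 1. Another 3 were neighbouring windows on chromosome X (2903970 to 65534775). Their medians ran from 0.689 to 0.952 in Kir2.1 and from 0.833 to 0.917 in the libraries labelled Kv1.5. Chromosome 19 held 4 (between 36383120 and 54194536), and chromosomes 4, 10 and 18 held 1 each. Windows 0.4 or more from 0 held 26.9% of the genes changed in Kir2.1 and 15.5% of tested genes, and 30.9% and 23.2% for the libraries labelled Kv1.5. Between the libraries labelled Kv1.5 and Kir2.1 the SD was 0.202 and 9 windows lay 0.4 or more from 0, against at most 0.108 and 1 in permuted orders. These windows held 7.71% of the genes changed between these groups and 4.73% of tested genes. In each comparison the windows were picked by the fold changes of the same genes, so a higher share of changed genes follows from that choice.

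**Figure D4:**
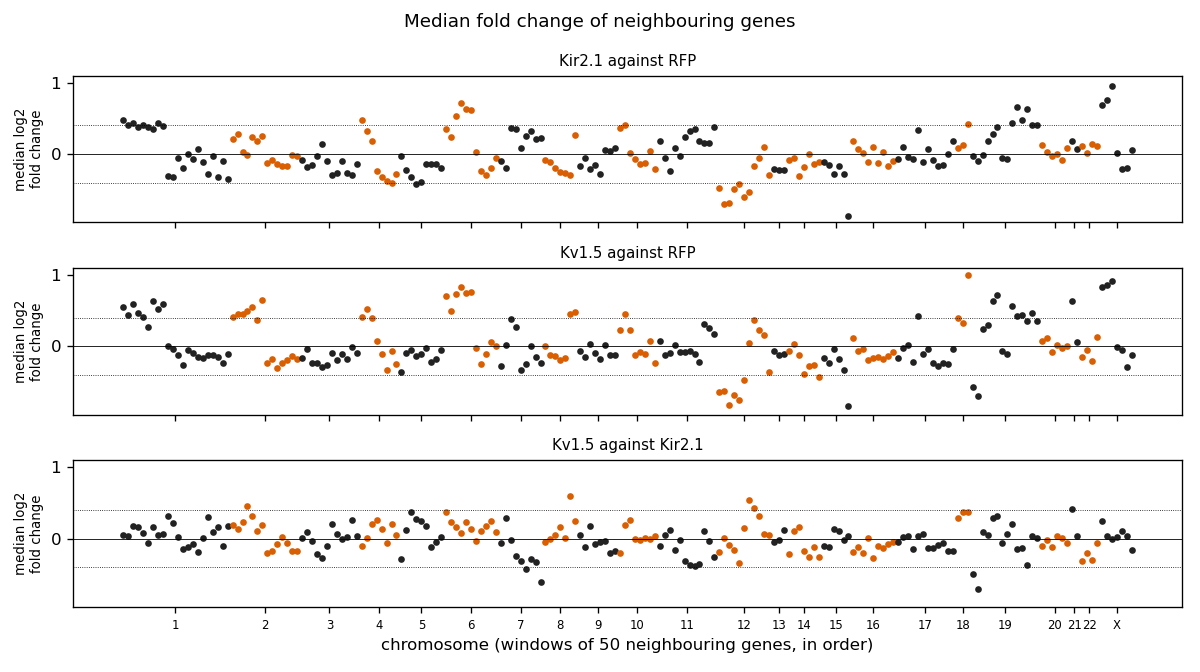
Median log2 fold change of 204 windows of 50 neighbouring genes in chromosome order, for each comparison. Each point is a window, colours alternate by chromosome, and dotted lines mark 0.4 and -0.4. Runs of windows on chromosomes 1, 6, 12 and X are displaced alike in both comparisons against RFP.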

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

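The tests on the replication and mitosis genes here were chosen after the result was seen. Several gene lists differed between the libraries labelled Kv1.5 and Kir2.1 by camera's test of that difference with the preset correlation, and none with an estimated correlation. Median log2 differences, Kv1.5 minus Kir2.1, were 1.76 for inflammatory genes, 1.63 for unfolded protein and stress response genes, 1.17 for immediate early genes and 0.495 for ERK output genes. The median was -1.04 for mitosis genes, -0.962 for cholesterol synthesis genes, -0.914 for replication genes, -0.694 for collagens and matrix glycoproteins, and -0.462 for hypoxia and glycolysis genes. In addition 55 genes changed against RFP in opposite directions, where independent lists would give 567. All were past the threshold between the groups, which nearly follows from opposite calls in the same fit. A member of the fixed lists among them, picked after its values were seen, was COL5A1 (0.81 in Kir2.1 and -1.04 in the libraries labelled Kv1.5).

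The replication and mitosis genes, 49 in all, were lower in the libraries labelled Kv1.5 than in RFP, with a median log2 fold change of -1.28. A single library did not make the pattern: the median was -1.95 without replicate 2, with 46 genes below 0, and -1.04 without replicate 3, with all 49 below 0. Scaling moves all genes of a library alike, yet these genes lay at least 1.03 below the median of all tested genes (difference -1.03 without replicate 3), while RLE and upper quartile scaling moved that median by only -0.0034 and -0.0062 and decide nothing. A channel effect stays open and untested, because KCNA5 had 0 counts in these libraries, and no measurement of culture density or growth was used here. The group could therefore differ in growth for reasons other than its construct, and nothing in these libraries separates these explanations.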

How the results depend on the processing

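RLE and upper quartile scaling changed no list call and no call of a gene named by the rule and moved the median of all genes by only -0.0287 to 0.0254 (log2), which tests little, and no called result among these reversed under any setting run. An adjusted p under 0.01 left 1681, 3123 and 970 genes for Kir2.1 against RFP, Kv1.5 against RFP and Kv1.5 against Kir2.1, 1468 and 932 by more than 2-fold for the first and the last, and 1055 genes shared against RFP, by construction of the stricter threshold. With 1 library left out, Kir2.1 against RFP gave 1975 to 4519 genes, Kv1.5 against Kir2.1 gave 1384 to 3861 (1248 to 2979 by more than 2-fold), and 1363 to 2509 genes were shared. A fit without 1 library labelled Kv1.5 rests on a lone sample assumed to vary like the other groups, and Kv1.5 replicate 1 could not be left out because it was not in the fit. For Kir2.1 against RFP the number of called lists went from 4 to 7 with no filter on low counts, to 2 with fry, and to 2 to 7 with 1 library left out, and the cause was not tested. With an estimated correlation 0 lists were called in each comparison, against 4, 12 and 9 with the preset correlation. Fry called 2, 11 and 7. For the lists called in Kv1.5 against RFP, the estimates ran from -0.0183 (epithelial markers) to 0.705 (mitosis genes), against the preset 0.01. The epithelial list lost its call with an estimate below the preset value. The size of the estimates thus does not account for every loss. For the simulated ERK output genes, drawn independently of each other, camera's adjusted p also went from 2.23e-10 to 0.0464 with an estimated correlation. A call lost with that setting therefore does not by itself show that members vary together, and other causes were not tested. DESeq2 called 3975, 5992 and 3452 genes and limma voom 3412, 5604 and 2834.

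The replicate block gave 3707, 5565 and 2729 genes in the 3 comparisons. Replicate numbers did not pair the libraries in a uniform way. Deviations of RFP and Kir2.1 libraries of the same number correlated at 0.286, -0.191 and 0.315. RFP replicate 1 with Kir2.1 replicate 3 gave -0.361, and RFP replicate 3 with Kir2.1 replicate 1 gave -0.309. Libraries labelled Kv1.5 gave 0.0964 and -0.0494 with RFP libraries of their number, and -0.0233 and 0.173 with those of Kir2.1. A batch shared by replicates 1 or 3 of RFP and Kir2.1 is therefore not excluded. Under the block 6 calls were lost among 83 named gene results, called or not (CSF3 and LCN2 for Kir2.1 against RFP, ATF3 and KIF20A for Kv1.5 against RFP, CCNA2 and MMP3 for Kv1.5 against Kir2.1). That does not by itself show a weaker effect. With the median of its window of 50 neighbouring genes taken off each gene, a setting chosen after seeing the data, 1860, 3271 and 1709 genes changed by more than 2-fold, of which 1792, 3113 and 1625 were among those counted before. Only the fold size was altered. The adjusted p-values were those of the main fit, so the calls themselves were not retested. At the depth and replicate number of these libraries, 34.4% of simulated 2-fold changes were recovered for Kir2.1 against RFP, and depth was not varied. The simulation changed a far smaller share of genes than the 20.5% called in this comparison, which makes the adjusted threshold stricter. The recovered share is therefore not the sensitivity in these data.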

Other observations

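The tests on KCNA5 were chosen after its counts were seen, and those on windows of neighbouring genes after the lists of changed genes were seen. Other ion transport genes of the fixed lists, picked after their values were seen, also differed from RFP. The sodium pump subunit ATP1B1 rose by 1.02 in Kir2.1 and 2.38 in the libraries labelled Kv1.5, and the calcium pump ATP2B1 rose by 2.01 in the latter. KCNN4, a calcium-activated potassium channel, rose by 1.15 in Kir2.1. In Kir2.1 and the libraries labelled Kv1.5, log2 fold changes were -4.21 and -5.18 for KCNJ8 and -2.70 and -3.24 for KCNQ3. Camera called neither ion channel list in any comparison with the preset correlation.

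KCNA5 had 0 counts in both libraries labelled Kv1.5. Depth is argued against, since the lowest KCNJ2 level in a Kir2.1 library was 21600 times the level that 0 counts allow for KCNA5. A swap with a library that holds counted KCNA5 reads is argued against, since the highest KCNA5 count in any library was 1. If transgene reads were not counted as KCNA5, this test could not find a swap, for example with an RFP library. A transgene whose reads were not counted as human KCNA5, for example a recoded sequence, cannot be excluded: all KCNA genes together had 1 count in these libraries, and neither reads nor construct sequence were used here. A wrong label, or cells that lost the transgene, stays open too.

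Both groups shared large changes against RFP, such as CDH11, MMP1 and SPARC. Replicate spread in the shared RFP libraries does not account for the covariance of log2 fold changes, 1.46 against at most 0.0663 in simulations. The simulations gave all groups the same mean, so they cannot tell whether the RFP cells themselves differ. Displaced runs of neighbouring genes are consistent with a segmental copy number difference from the RFP cells, with an SD of window medians of at least 0.287 against at most 0.134 in permuted orders, although permuted orders ignore local co-regulation. The libraries labelled Kv1.5 and Kir2.1 also differed from each other in such runs, with an SD of 0.202 against at most 0.108, so the runs do not set apart the RFP cells alone. GC content and transcript length are argued against as the cause of the runs against RFP, since the SD there stayed at 0.248 or more with both taken out, and between the libraries labelled Kv1.5 and Kir2.1 it was 0.175 against at most 0.106 in permuted orders, which leaves them open as part of those runs. Shifts of this size would not by themselves give the largest gene changes. Whether the groups may descend from different subpopulations of the line was not tested, since karyotype or DNA data were not used here. Per the labels, both other groups carried EGFP and the control RFP. The fluorescent protein therefore cannot be told apart from the channel constructs in the shared changes. An effect of potassium channel expression remains open.

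For the 6 RFP and Kir2.1 libraries, 10 splits into groups of 3 are too few for a share under 0.05. The real split gave 3418 genes and 2234 by more than 2-fold and was the 1 split with as many, and the highest other split gave 0 and 0. Each other split mixed RFP and Kir2.1 libraries in both groups, so the real difference added to the spread within them. Their 0 calls are therefore no measure of chance.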
